A study of Mus musculus with 9 samples.

How the data were processed

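The 9 libraries came from ear skin of C57BL/6 mice. Per the labels' protocols, the bacterium was grown at 37 °C for 18 h in tryptic soy broth and swabbed on the ears, and total RNA of a dissected skin region was used at 500 ng for Tecan's Universal Plus library kit. Sequencing was on an Illumina NextSeq with 75 cycles. Per the submitters' processing notes, STAR, HOMER and DESeq2 were among the tools and mm10 was the genome build. Their versions, the role of each and the gene annotation are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

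The deposited table gives transcript abundance as TPM per gene and library, 25124 genes in all, rounded to 3 decimals, with gene positions on mm10. TPM divides each gene's reads by its length and scales them to a library total, so a rise in abundant genes lowers all others. The listed genes of each library summed to between 696393 and 728933 TPM, less than the full TPM total. The sources used here do not give the reason, such as features counted in the total but not listed. The ribosomal RNA entries Rn45s and Mir6236 took between 30.6% and 40.2% of the listed TPM. Their share was 33.7% ± 2.25 with the bacterium alone and 34.9% ± 4.26 with the antibody (SD, n = 5 and n = 4; exact two-sided permutation p = 0.619). TPM keeps no read totals, so no counting intervals are given and no count model was run. The worth of 1 read relative to the first library was recovered from genes with low values and lay between 0.845 and 1.13. With these factors, 52.5% of 3183 low genes had values within 0.12 reads of whole numbers in every library, against 0.0628% with the factors shuffled. This gives read numbers for single genes with low values and not the depth. They are the smallest whole numbers that fit a gene's values, so the true numbers can be larger. Xist lay between 402 and 504 TPM and the Y-linked Ddx3y at or below 0.0970 TPM in all 9 libraries.

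Genes with at least 1 TPM in at least 4 libraries were kept, which left 15704, of which 14023 are protein-coding per the table's annotation. The groups were compared on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, by linear models with empirical Bayes variances that follow the mean expression and no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. All tests were two-sided with a threshold of 0.05. The pseudocount of 1 makes a fold change understate the change of genes with low TPM, and fold changes are on that scale throughout. Given are the mean TPM and SD per group and the log2 fold change of anti-CTLA-4 minus the bacterium alone.

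Before the data were examined, 50 gene lists were fixed for immune cells, epidermal programs, other cell types of the ear and signs of RNA quality. Of these, 46 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Counts within a list cover the members that passed the filter, which were few for the hair follicle (7 of 21), neutrophils (8 of 16), cytotoxic lymphocytes (10 of 19), B and plasma cells (3 of 14) and red cells and platelets (5 of 9). The filter does not use the groups, but a gene with a low level can pass it because it changed, so such counts describe the tested members only. The gamma-delta T cell list (2 tested genes), the eosinophil and basophil list (1) and the list of mitochondrially encoded genes (0) were not tested, and the sex-linked list served only as a check of the samples. T cell receptor constant genes, immunoglobulin constant genes, Flg and the mitochondrially encoded genes were not analysed here. Several genes stand in more than 1 list, such as Ctla4, Icos, Cd28 and Saa3. A panel of 16 genes was compared by an exact permutation test over all splits of the 9 libraries into 5 and 4. The test was run on mean log2(TPM + 1) and, as an alternative, on mean TPM.

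Named genes followed a rule fixed before the data were examined. It took the 12 largest increases and the 12 largest decreases among called genes whose groups did not overlap, passing over microRNA, small nucleolar RNA and unnamed genes. It also took up to 4 tested members with the smallest p of each list described, and the panel. Where few genes were called in a list or fit, those outside the rule were named too, and the text says so. Some genes that the rule takes are not reported here. Lists tested that the text gives only as counts have no named members under the rule.

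The alternatives tried were other pseudocounts and expression filters, 3 other scalings, other variance settings, array weights, the replicate number as a block, covariates for skeletal muscle and hair follicle content, leaving out each library in turn, a threshold of 0.1, and other list tests. A fit on protein-coding genes and a correction for GC content and transcript length were added after the data were seen. The correction used the longest transcript of each gene in GENCODE M21 and covered 99.2% of tested protein-coding genes, 13904 in all. The limma and camera steps were tested on simulated data of this comparison with 15704 genes, 200 of them changed. They recovered 88% of genes changed by 1 and 96% of those changed by 2 on the log2 scale, called 8 unchanged genes, and called the shifted list and 0 of the others. Smaller changes were not simulated. In the real data the median log2 fold change was 0.60 among genes that rose and -0.40 among those that fell, so recovery at those sizes is unknown. The simulated genes were drawn independently of each other, while the estimated correlation within the real lists reached 0.834. The simulation therefore cannot show how often camera at its preset correlation calls lists falsely in these data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for the figures.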

Results

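Whole ear skin of C57BL/6 mice was profiled by RNA sequencing after topical association with Staphylococcus epidermidis strain LM087, a bacterium that lives on skin. The 9 libraries fall into 2 groups. In 5 libraries the mice received the bacterium alone, and in 4 they also received an anti-CTLA-4 antibody, a checkpoint inhibitor directed against the T cell receptor CTLA-4 that restrains T cell activation. The bacterial suspension was applied every other day, and a skin region of about 1 mm was taken on day 8. The comparison asks how skin carrying the bacterium differs when the checkpoint is blocked. Skin without the bacterium, and skin given the antibody alone, were not analysed here. The values are TPM, a length-scaled measure of transcript abundance, for 25124 genes. The 9 libraries listed between 19639 and 20088 genes above 0 TPM and summed to between 696393 and 728933 TPM over the listed genes. TPM values hold no read totals, so the sequencing depth is unknown. The labels number the replicates without saying that each came from a separate animal, so the p-values measure the spread between these samples, which may be partly technical.

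In skin given anti-CTLA-4, 13 of 18 tested T cell genes, 14 of 18 monocyte and macrophage genes, 6 of 16 neutrophil genes (8 of which passed the expression filter), 17 of 22 type I interferon response genes and all 7 tested MHC class II genes rose. Of 19 cholesterol synthesis genes, 13 fell, as did 6 of 12 genes of the epidermal ceramide barrier and 4 of 21 hair follicle genes (7 of which passed the filter). These are calls of single genes, since camera called 0 of the 46 lists when the correlation between genes was estimated (lowest adjusted p = 0.157 with an estimated correlation). Of 15704 genes tested with limma, 1124 rose and 704 fell at a Benjamini-Hochberg adjusted p under 0.05, which is 11.6% of the genes tested. Changes of at least 2-fold were more frequent upward, with 197 genes higher and 21 lower, and 11 of those 21 were microRNA or small nucleolar RNA genes. The median log2 fold change was 0.60 among the genes that rose, -0.40 among those that fell and -0.014 over all tested genes. The values of the 2 groups did not overlap for 2262 genes, or 14.4% of those tested, where chance gives 1.59%. The first principal component held 27.1% of the variance and placed the 5 libraries of the bacterium alone between -36.7 and -6.13 and the 4 anti-CTLA-4 libraries between 20.0 and 27.4.

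Cxcl2, a neutrophil-attracting chemokine (mm10 chromosome 5, 90903899 to 90905938, plus strand), had the largest increase among named genes and rose from 3.88 ± 5.58 to 31.5 ± 11.02 TPM (SD, n = 5 and n = 4), with a log2 fold change of 3.32 ± 0.65 (SE) and a limma adjusted p of 0.0128. Saa3, an acute phase protein, rose by 2.74 on the log2 scale, and the cornified envelope precursor Sprr2a3 by 2.58. The chemokines Ccl3, Cxcl5 and Cxcl3 rose by 2.39, 2.32 and 2.19. Cd8a, which encodes the CD8 alpha chain of cytotoxic T cells (mm10 chromosome 6, 71373427 to 71379171, plus strand), rose from 1.85 ± 0.963 to 11.5 ± 3.68 TPM (SD, n = 5 and n = 4), a log2 change of 2.16 ± 0.27 (SE) at a limma adjusted p of 0.00280. Il1b, the precursor of the cytokine interleukin-1 beta, rose from 7.65 ± 7.17 to 27.2 ± 1.31 TPM. The cystatin-family genes Cstdc5 and Stfa1 rose by 2.32 and 2.07, and the immune cell genes Slfn1 and Ly6c2 by 2.18 and 2.16. Sprr2a3, Stfa1, Cstdc5, Slfn1 and Ly6c2 have close relatives in the genome, and how shared reads were assigned is not given in the sources used here, so their values are uncertain. The calls of Cstdc5, Il1b, Stfa1 and Ly6c2 ended in 7, 7, 6 and 5 of the 9 fits that left out 1 library, with limma adjusted p-values of up to 0.113, 0.0656, 0.0774 and 0.0871.

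The largest decreases among named genes were smaller, with microRNA, small nucleolar RNA and unnamed genes passed over. The water channel gene Aqp5 (mm10 chromosome 15, 99591028 to 99594829, plus strand) fell from 5.70 ± 2.58 to 0.990 ± 0.578 TPM (SD, n = 5 and n = 4), a log2 change of -1.71 ± 0.28 (SE) at a limma adjusted p of 0.00623. Flg2, a filaggrin-family protein of the cornified layer (mm10 chromosome 3, 93197273 to 93221376, plus strand), fell from 562 ± 153 to 234 ± 62.5 TPM, a log2 change of -1.26. Cyp2g1, a cytochrome P450, fell from 17.5 ± 5.07 to 5.94 ± 3.01 TPM. Ereg, which encodes the growth factor epiregulin, fell from 22.1 ± 3.19 to 11.9 ± 1.20 TPM. The inner root sheath keratin Krt73 fell from 12.6 ± 3.16 to 6.16 ± 1.38 TPM, and S100a3 from 2.82 ± 1.01 to 0.831 ± 0.370 TPM. Tspear, Serpina12, Fmo2, Nhlrc1, Prr9 and Kcng4 fell by between 0.83 and 1.04 on the log2 scale. The call of S100a3 ended without anti-CTLA-4 replicate 1 or 4 (limma adjusted p of up to 0.0531). The calls of Fmo2 and Prr9 ended in 4 and 5 of the 9 fits that left out 1 library, with limma adjusted p-values of up to 0.0730 and 0.0790.

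The balance of rises and falls depended on the scaling, and the number of calls on the libraries and covariates in the fit. Quantile normalization called 1314 genes higher and 1429 lower, scaling to a common median 1302 and 1313, and leaving the 50 most abundant genes out of the total 1198 and 1301. Among protein-coding genes, the fit called 1244 higher and 813 lower without, and 1304 and 1468 with, a correction for GC content and length. The first tested 14023 genes and the second 13904, so the sets of genes differ slightly too. The count of lower genes dropped to 414, 352 and 397 without replicates 1, 2 and 4 of the bacterium alone, and to 337, 406 and 377 without anti-CTLA-4 replicates 1, 2 and 4. The count of higher genes dropped to 706 without anti-CTLA-4 replicate 3. With the mean of the skeletal muscle list as a covariate, limma called 9 genes higher and 3 lower (Cyp51, Grhl3 and Mir3112), and with the mean of the hair follicle list 1 higher (Cd6) and 1 lower (Mir3112). The mean log2(TPM + 1) of these lists was itself 6.22 ± 0.216 and 5.87 ± 0.208 for muscle and 2.98 ± 0.349 and 2.36 ± 0.216 for the hair follicle (SD, n = 5 and n = 4). All 1828 changed genes kept their direction in both fits. Their median absolute log2 change went from 0.47 to 0.47 and 0.45, while its median SE grew from 0.10 to 0.14 and 0.16, and the genes with an unadjusted p under 0.05 dropped from 4145 to 2558 and 1820. Grhl3 and Mir3112 were chosen after their values were seen.

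Most tested T cell genes rose. Of 18 tested, 13 rose (16 adjusted over the list alone), none fell and 5 were not called. Cd2, an adhesion receptor of T cells, rose from 2.28 ± 0.732 to 9.11 ± 1.38 TPM (SD, n = 5 and n = 4), the kinase gene Lck from 2.77 ± 0.587 to 8.95 ± 1.60 TPM, and Cd6 from 0.456 ± 0.147 to 2.27 ± 0.408 TPM. Cd4, the marker of helper T cells, had 3.41 ± 0.565 and 4.91 ± 1.51 TPM and was not called (limma adjusted p = 0.190), although it passed without anti-CTLA-4 replicate 4 (limma adjusted p = 0.0419). The list was called higher by camera (adjusted p = 4.33e-14; adjusted p = 0.157 with an estimated correlation). Among 10 tested genes (of 19 in the list) of cytotoxic lymphocytes and natural killer cells, 6 rose (9 adjusted over the list alone). Nkg7, a granule protein, rose from 10.4 ± 2.16 to 29.0 ± 5.70 TPM, the death ligand Fasl from 0.338 ± 0.213 to 1.98 ± 0.258, the granzyme Gzma from 0.355 ± 0.228 to 2.19 ± 0.877, and the receptor gene Klrc1 from 0.902 ± 0.472 to 3.36 ± 0.990. This list was also called higher (camera adjusted p = 1.58e-07; adjusted p = 0.157 with an estimated correlation). Without the filter 18 of its genes were tested and 6 were called higher. The filter can keep a gene with a low level because it rose. In this list 3 tested genes, all 3 called, had a mean under 1 TPM with the bacterium alone and of at least 1 TPM with the antibody. The same held for 3 tested T cell genes, all 3 called.

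Ctla4 itself, the gene of the receptor the antibody binds (mm10 chromosome 1), rose from 3.53 ± 1.52 to 13.3 ± 0.788 TPM (SD, n = 5 and n = 4), a log2 change of 1.72 at a limma adjusted p of 0.00281. In the list of co-stimulation and checkpoint genes, 7 of 12 rose (11 adjusted over the list alone), among them Icos from 2.43 ± 1.18 to 8.02 ± 0.920, Cd28 from 1.77 ± 0.346 to 3.99 ± 0.614 and Havcr2 from 3.67 ± 0.622 to 6.88 ± 1.01 TPM. Camera called the list higher (camera adjusted p = 5.39e-08; adjusted p = 0.157 with an estimated correlation). Of 11 regulatory T cell genes, 5 rose (7 adjusted over the list alone). These were Ctla4, the chemokine receptor Ccr8 (0.377 ± 0.216 to 2.10 ± 1.10 TPM), the integrin Itgae (2.87 ± 0.256 to 4.36 ± 0.512), the lineage factor Foxp3 (4.70 ± 0.733 to 6.57 ± 0.636) and Tnfrsf4 (8.22 ± 1.05 to 11.4 ± 1.49), the last named after its values were seen. The calls of Foxp3 and Tnfrsf4 ended in 6 of the 9 fits that left out 1 library (limma adjusted p of up to 0.0770 and 0.0981). The regulatory T cell list was called higher (camera adjusted p = 3.46e-05; adjusted p = 0.157 with an estimated correlation).

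Most tested genes of type 1 lymphocytes rose, and type 17 lymphocyte genes were not called as a list. Of 8 tested type 1 genes, 5 rose (6 adjusted over the list alone). The chemokine receptor Cxcr3 rose from 2.50 ± 0.961 to 9.03 ± 1.96 TPM (SD, n = 5 and n = 4), the interleukin-18 receptor genes Il18r1 and Il18rap from 3.10 ± 0.632 to 8.83 ± 1.66 and from 3.15 ± 1.60 to 10.1 ± 1.88, and the transcription factor Stat4 from 0.410 ± 0.137 to 1.44 ± 0.217. Cxcr6, named after its values were seen, rose from 15.5 ± 1.13 to 26.1 ± 5.47. The type 1 list was called higher (camera adjusted p = 1.33e-05; adjusted p = 0.157 with an estimated correlation). Ifng, the gene of interferon gamma, had 0.566 ± 0.826 and 1.23 ± 0.200 TPM and was not called (limma adjusted p = 0.192). Replicate 5 of the bacterium alone held 2.04 TPM of Ifng. Without it the means were 0.199 ± 0.0832 and 1.23 ± 0.200 TPM (SD, n = 4 and n = 4), Ifng was below the expression filter, and the exact permutation p was 0.0286, the smallest that test can give (adjusted p = 0.0457 over the 16 panel genes). Of 9 tested type 17 genes, from a list of 13, Ccr6 rose (1.52 ± 0.525 to 2.76 ± 0.431 TPM; 1 gene adjusted over the list alone) and 8 were not called, including the receptor gene Il23r (1.17 ± 0.249 and 1.57 ± 0.427 TPM). The call of Ccr6 ended in 7 of the 9 fits that left out 1 library (limma adjusted p of up to 0.0990), and the type 17 list had a camera adjusted p of 0.725. With the bacterium alone, the mean log2(TPM + 1) per library was 3.56 to 3.72 for the tested type 17 genes and 1.49 to 1.85 for T cell genes. The cells that expressed the tested type 17 genes were not determined, so the list may not reflect lymphocytes alone. Il17a, Il17f, Il22 and Il6 were below the expression filter. Their TPM values corresponded to 23, 15, 11 and 26 inferred reads in total over the 5 libraries of the bacterium alone and to 15, 44, 7 and 31 over the 4 anti-CTLA-4 libraries. These are the smallest read numbers that fit. Il17f fitted least closely, with a largest gap to whole numbers of 0.116 reads against the tolerance of 0.12. By an exact two-sided permutation test over all splits of the 9 libraries into 5 and 4, their p-values were 0.921, 0.0952, 0.778 and 0.333. Replicate 5 of the bacterium alone held 16 of the 23 Il17a reads and 10 of the 15 Il17f reads. Without it the totals were 7 against 15 reads for Il17a (exact permutation p = 0.200), 5 against 44 for Il17f (p = 0.0286; adjusted p = 0.0457 over the panel), 7 against 7 for Il22 (p = 0.914) and 15 against 31 for Il6 (p = 0.0857). The adjusted p of 0.0457 for Ifng and Il17f rests on 10 panel genes that tie at the smallest possible p.

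Most monocyte and macrophage genes and some neutrophil genes also rose, while dendritic and Langerhans cell genes were not called. Of 18 monocyte and macrophage genes, 14 rose (17 adjusted over the list alone). Ccr2, a chemokine receptor of blood-derived monocytes, rose from 47.4 ± 12.3 to 129 ± 15.5 TPM (SD, n = 5 and n = 4), Itgam from 3.53 ± 0.673 to 10.6 ± 1.53, Ms4a6c from 17.1 ± 3.76 to 46.2 ± 5.76, and the mannose receptor Mrc1 from 14.7 ± 1.65 to 31.6 ± 5.54. As a list they were called higher (camera adjusted p = 8.46e-14; adjusted p = 0.157 with an estimated correlation). Of 16 neutrophil genes in the list, 8 passed the filter and 6 rose (6 adjusted over the list alone), with Csf3r from 2.93 ± 1.43 to 9.12 ± 1.68, Clec4d from 2.03 ± 0.837 to 5.75 ± 0.663, Fpr2 from 0.454 ± 0.392 to 2.14 ± 0.334 and Stfa2l1 from 0.199 ± 0.141 to 1.66 ± 0.607 TPM. That list was called higher too (camera adjusted p = 2.32e-05; adjusted p = 0.157 with an estimated correlation), but not at a TPM minimum of 5 (camera adjusted p = 0.0523). The filter can keep a gene with a low level because it rose, and 4 of the 8 tested genes, 3 of them called, had a mean under 1 TPM with the bacterium alone and of at least 1 TPM with the antibody. Without the filter all 16 were tested and 6 were called higher. Of 16 genes of microbial pattern recognition and the inflammasome, 11 rose (13 higher and 1 lower adjusted over the list alone), among them Nlrp3 from 1.34 ± 0.434 to 4.27 ± 0.292, Tlr1 from 2.92 ± 1.10 to 8.41 ± 1.02, Tlr9 from 12.1 ± 1.98 to 28.05 ± 5.02 and Aim2 from 2.67 ± 0.395 to 5.37 ± 1.07 TPM (camera adjusted p = 1.74e-08; adjusted p = 0.157 with an estimated correlation). None of 13 dendritic and Langerhans cell genes was called by limma over all genes or adjusted over the list alone, and the list had a camera adjusted p of 0.123.

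Of 26 chemokine genes, 8 rose (9 adjusted over the list alone) and 18 were not called. Ccl8 rose from 146 ± 37.3 to 381 ± 122 TPM (SD, n = 5 and n = 4), Cxcl12 from 51.0 ± 8.83 to 84.4 ± 7.16, Cxcl5 from 1.83 ± 1.72 to 11.7 ± 3.41 and Ccl3 from 1.48 ± 1.84 to 10.4 ± 4.97. As a list they were called higher (camera adjusted p = 8.39e-06; adjusted p = 0.236 with an estimated correlation). Among 11 inflammatory cytokine genes, Il1b and Osm rose (5 genes adjusted over the list alone), and the list was not called (camera adjusted p = 0.0515). Osm went from 1.58 ± 1.07 to 4.66 ± 0.419 TPM. Tnf, with 6.09 ± 2.27 and 10.9 ± 2.39 TPM, was not called over all genes tested (limma adjusted p = 0.0514), but passed without replicate 5 of the bacterium alone (limma adjusted p = 0.0144). Camera called the cytokine list higher without replicate 1, 3 or 5 of the bacterium alone or without anti-CTLA-4 replicate 2, with an adjusted p of down to 0.0104. It also called it higher without an expression filter and with each of the 3 other scalings, with an adjusted p of down to 0.0208.

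Most type I interferon response and MHC presentation genes rose, while no gene of the interferon-gamma response list was called. Of 22 type I interferon response genes, 17 rose (22 adjusted over the list alone), with a median log2 fold change of 1.00. The antiviral genes Bst2, Mx1, Oas3 and Oasl1 rose from 9.43 ± 1.94 to 18.9 ± 1.60, from 4.22 ± 1.75 to 10.6 ± 1.78, from 1.20 ± 0.553 to 3.57 ± 0.361 and from 0.909 ± 0.367 to 2.91 ± 0.316 TPM (SD, n = 5 and n = 4). The list was called higher (camera adjusted p = 4.33e-14; adjusted p = 0.208 with an estimated correlation). In the interferon-gamma response list, all 20 tested genes had a positive log2 fold change, with a median of 0.68, but none was called by limma over all genes or adjusted over the list alone. Cd274, which encodes the checkpoint ligand PD-L1, had 13.2 ± 6.29 and 21.5 ± 2.75 TPM (limma adjusted p = 0.0950), and passed without replicate 5 of the bacterium alone (limma adjusted p = 0.00777). Camera called the list higher (adjusted p = 0.000309; adjusted p = 0.445 with an estimated correlation). Of 13 genes of MHC class I presentation, 11 rose (12 adjusted over the list alone), including B2m from 422 ± 76.1 to 822 ± 163, H2-K1 from 410 ± 56.0 to 656 ± 119 and H2-D1 from 554 ± 57.3 to 862 ± 128 TPM (camera adjusted p = 1.24e-08; adjusted p = 0.224 with an estimated correlation). All 7 tested MHC class II genes, of 9 in the list, rose (7 adjusted over the list alone), with Cd74 from 373 ± 27.5 to 588 ± 90.6, H2-Aa from 263 ± 21.8 to 416 ± 63.9 and H2-Eb1 from 105 ± 11.5 to 171 ± 26.1 TPM (camera adjusted p = 4.41e-07; adjusted p = 0.208 with an estimated correlation). The H2 genes are closely related, and reads could be split among them.

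**Figure D1:**
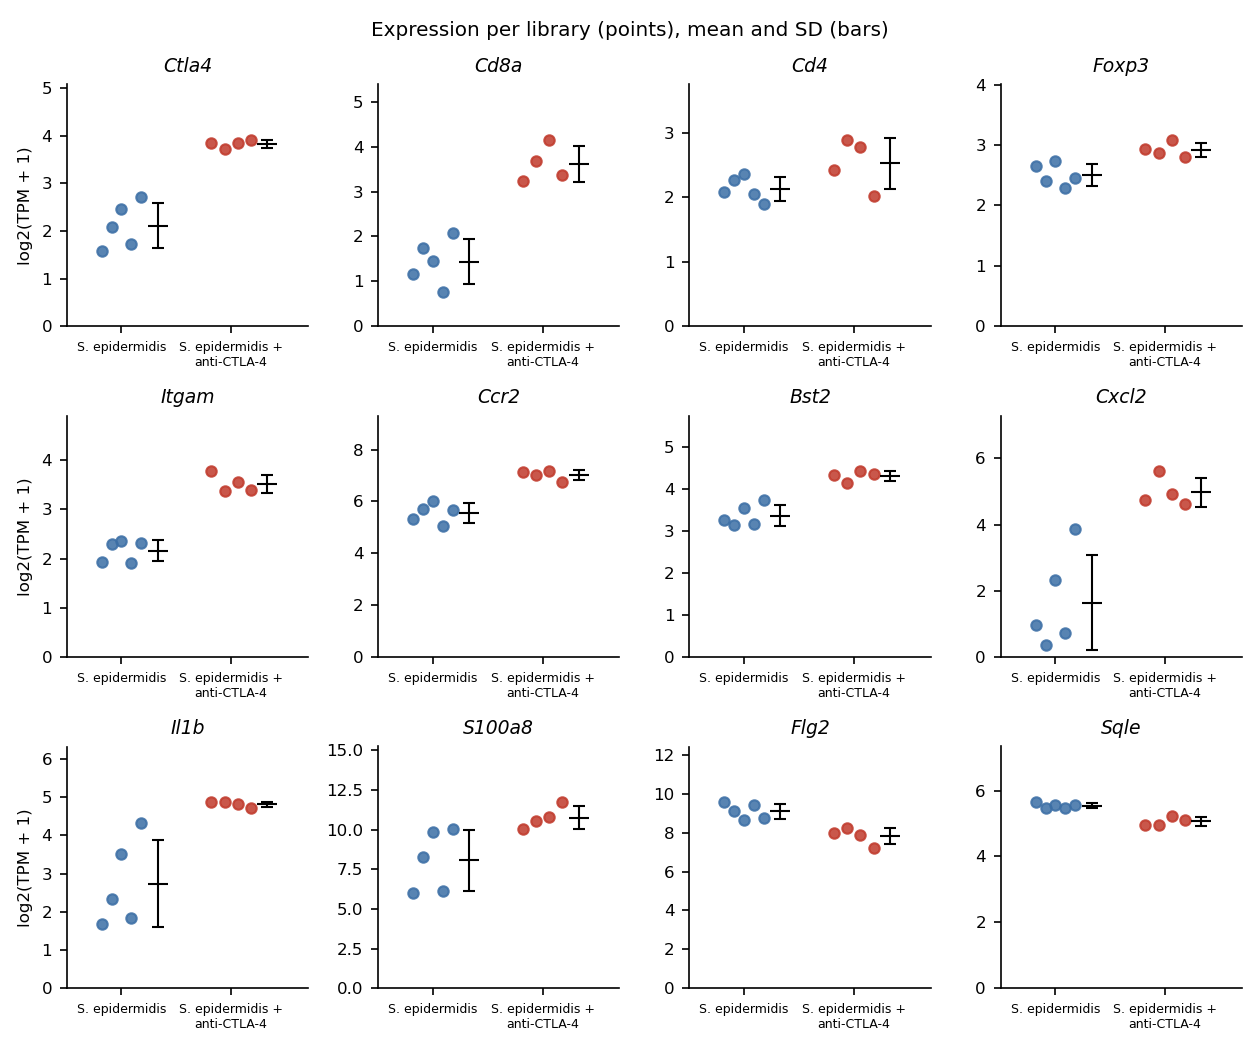
Each point is the log2(TPM + 1) of a library for 12 named genes, with the 5 libraries of S. epidermidis alone in blue and the 4 with anti-CTLA-4 in red, and black bars give each group's mean and SD. Ctla4, Cd8a, Itgam, Ccr2 and Bst2 are among the genes that separate the groups. S100a8 varies from 63.6 to 1031 TPM within the S. epidermidis group, which ends just below the lowest anti-CTLA-4 value of 1032 TPM.

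Most cholesterol synthesis genes fell, as did some genes of the ceramide barrier and the cornified envelope. Of 19 cholesterol synthesis genes, 13 fell (19 adjusted over the list alone) and 6 were not called, with a median log2 fold change of -0.39. Sqle, which encodes squalene epoxidase, fell from 45.6 ± 2.30 to 32.5 ± 3.11 TPM (SD, n = 5 and n = 4), Cyp51 from 48.2 ± 3.13 to 35.6 ± 3.08, Sc5d from 33.0 ± 3.23 to 23.5 ± 1.83 and Dhcr7 from 24.7 ± 1.82 to 18.4 ± 0.714. As a list they were called lower (camera adjusted p = 1.47e-11; adjusted p = 0.157 with an estimated correlation). Of 12 genes that make or export barrier ceramides, 6 fell (8 adjusted over the list alone), with the lipoxygenase genes Aloxe3 and Alox12b going from 31.4 ± 3.50 to 19.6 ± 1.36 and from 51.7 ± 8.48 to 36.7 ± 2.37, and the lipid transporter Abca12 from 31.6 ± 4.51 to 21.8 ± 2.11 TPM (camera adjusted p = 1.13e-05; adjusted p = 0.224 with an estimated correlation). The call of Alox12b ended without anti-CTLA-4 replicate 1 or 2 (limma adjusted p of up to 0.0641). Of 21 genes of differentiated keratinocytes and the cornified envelope, 5 fell, 1 rose and 15 were not called (13 lower and 1 higher adjusted over the list alone). Flg2, Dsg1a (275 ± 18.2 to 197 ± 23.2 TPM), Sbsn (2308 ± 327 to 1601 ± 218), Krt2 and Dsc1 fell. Krt1, a keratin of the first layers above the basal one, rose from 792 ± 229 to 1506 ± 301 TPM. Krt2 and Dsc1 were named after their values were seen. The calls of Krt2, Dsc1, Sbsn and Krt1 ended in 8, 6, 5 and 4 of the 9 fits that left out 1 library, with limma adjusted p-values of up to 0.0723, 0.0971, 0.0730 and 0.0621. The list was called lower (camera adjusted p = 8.62e-06; adjusted p = 0.371 with an estimated correlation). Of 11 basal keratinocyte genes, Col17a1 fell (181 ± 11.5 to 148 ± 12.4 TPM; 1 gene adjusted over the list alone) and 10 were not called (camera adjusted p = 0.0439; adjusted p = 0.418 with an estimated correlation). The call of Col17a1 ended in 6 of the 9 fits that left out 1 library and that of the list in 5 (adjusted p of up to 0.0831 and 0.0648).

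Genes of the lists for inducible epidermal programs were higher on average but varied widely among the libraries of the bacterium alone. The samples are whole skin, and the cells that expressed these genes, epidermal or immune, were not determined. All 22 tested genes of wound-type and hyperplastic epidermis had a positive log2 fold change, with a median of 1.14, but only Stfa1, Sprr2a1 and Sprr2a2 rose (4 genes adjusted over the list alone). Sprr2a1 and Sprr2a2 carry identical values in all 9 libraries (1.88 ± 1.61 to 7.47 ± 3.998 TPM; SD, n = 5 and n = 4) and count as 1 measurement. Their call ended in 7 of the 9 fits that left out 1 library (limma adjusted p of up to 0.0991). Krt6b, a keratin of wounded skin, had 59.0 ± 47.8 and 245 ± 86.9 TPM (limma adjusted p = 0.0529), and passed without replicate 3 or 5 of the bacterium alone (limma adjusted p of down to 0.0328). Krt6a had 84.2 ± 47.4 and 197 ± 56.0 TPM and Krt16 had 252 ± 187 and 664 ± 222 TPM, and neither was called (limma adjusted p = 0.0824 and 0.0965), although Krt16 passed without replicate 3 of the bacterium alone (limma adjusted p = 0.0388). Camera called this list higher (adjusted p = 6.27e-06; adjusted p = 0.378 with an estimated correlation). Of 21 tested genes in the list of interleukin-17-responsive epithelial genes, 5 rose, namely Saa3, Cxcl5, Cxcl3, Cxcl2 and Lcn2 (9 higher and 1 lower adjusted over the list alone). Lcn2, an iron-binding antimicrobial protein, went from 19.5 ± 10.5 to 53.4 ± 18.7 TPM, and its call ended in 7 of the 9 fits that left out 1 library (limma adjusted p of up to 0.102). The antimicrobial S100a8 and S100a9 had 476 ± 462 and 204 ± 200 TPM with the bacterium alone and 1904 ± 1018 and 630 ± 295 TPM with the antibody, and were not called (limma adjusted p = 0.0821 and 0.115). S100a8 passed without replicate 3 or 5 of the bacterium alone (limma adjusted p of down to 0.0433). Cxcl1 had 9.36 ± 9.47 and 12.2 ± 7.19 TPM and was not called. As a list they were called higher (camera adjusted p = 0.000292; adjusted p = 0.376 with an estimated correlation). All 27 cell cycle genes had a positive log2 fold change, with a median of 0.36, and 4 rose (18 adjusted over the list alone). These were Kif20a (15.5 ± 1.80 to 20.7 ± 2.54 TPM), Birc5 (10.4 ± 1.76 to 15.3 ± 3.06), Ccnb1 (6.21 ± 1.58 to 10.1 ± 1.89) and Cdk1 (6.65 ± 1.14 to 9.54 ± 1.505). Their calls ended in 7 or 8 of the 9 fits that left out 1 library (limma adjusted p of up to 0.124), and the list was called higher (camera adjusted p = 5.39e-08; adjusted p = 0.378 with an estimated correlation).

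**Figure D2:**
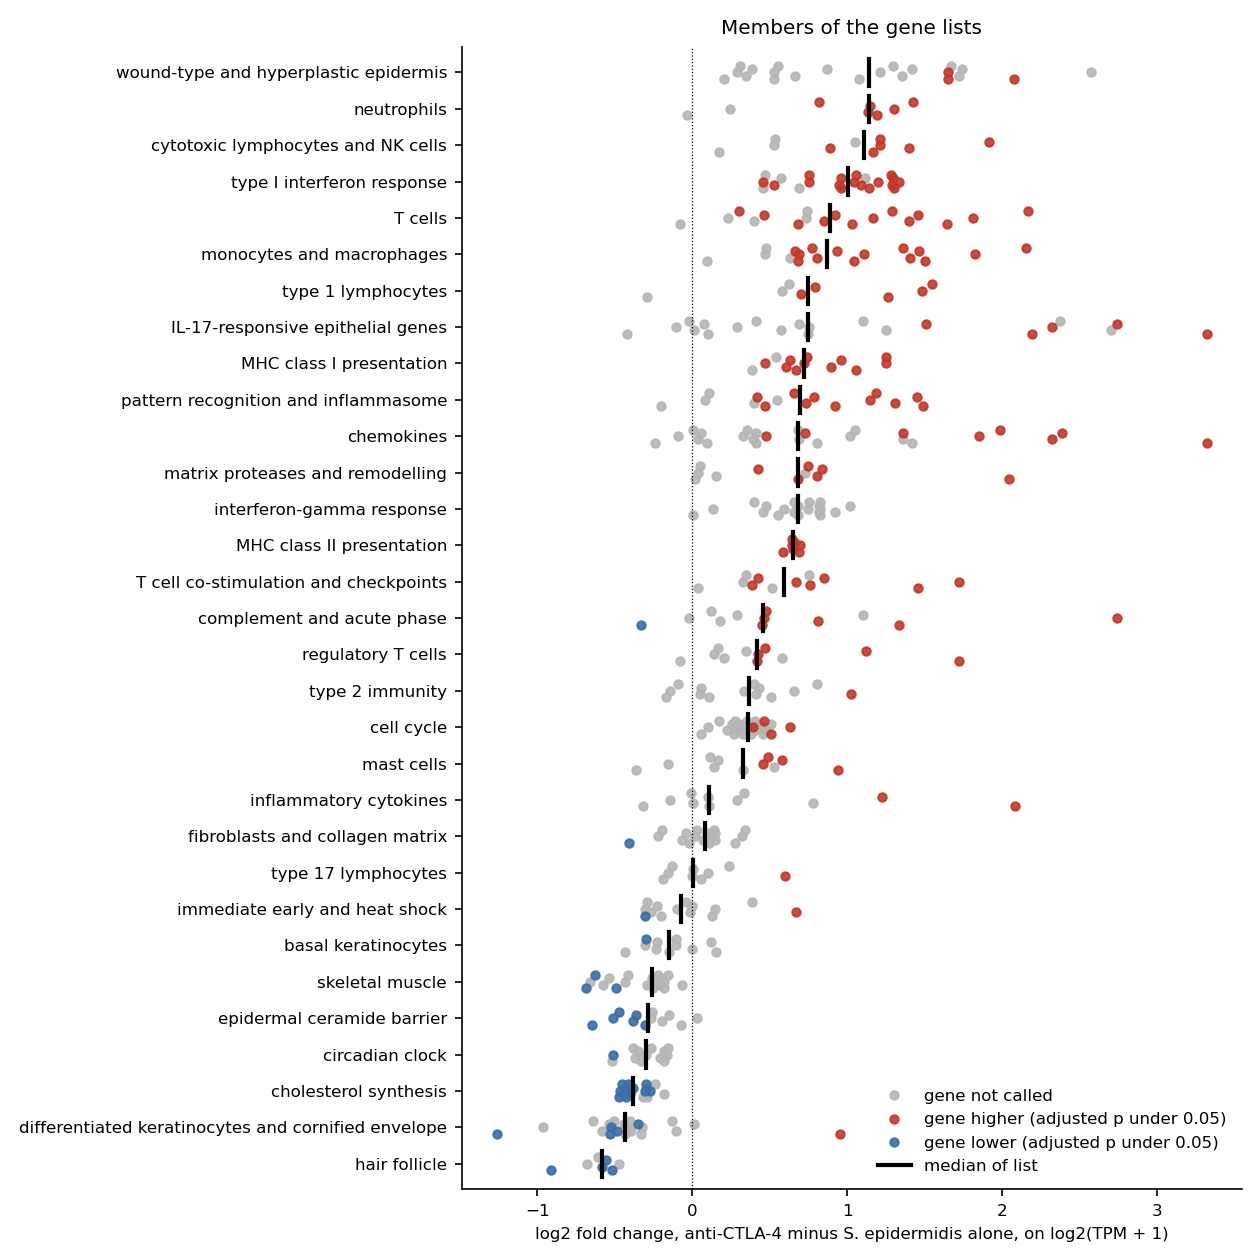
Each point is a tested member of a gene list, placed by its log2 fold change of anti-CTLA-4 minus S. epidermidis alone on log2(TPM + 1), red or blue where limma called it higher or lower and grey where it did not. Black lines are list medians, which run from -0.58 for the hair follicle to 1.14 for neutrophils and for wound-type epidermis.

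A few hair follicle and skeletal muscle genes fell, and some matrix remodelling genes rose. Of 21 hair follicle genes in the list, 7 passed the filter, of which 4 fell (4 adjusted over the list alone) and 3 were not called. Without the filter all 21 were tested and 3 were called lower. The transcription factor genes Hoxc13, Dlx3 and Msx2 fell from 4.47 ± 0.249 to 2.85 ± 0.559, from 51.8 ± 7.11 to 34.8 ± 3.73 and from 8.83 ± 1.74 to 5.56 ± 1.12 TPM (SD, n = 5 and n = 4), and Krt73 was the other gene to fall. Whether these values come from the follicle alone was not tested. The call of Msx2 ended in 6 of the 9 fits that left out 1 library (limma adjusted p of up to 0.102). The list was called lower (camera adjusted p = 0.000309; adjusted p = 0.208 with an estimated correlation). All 19 skeletal muscle genes had a negative log2 fold change, with a median of -0.26, and Actn3, Pvalb and Casq1 fell (6 genes adjusted over the list alone). Actn3, an actinin of fast fibres, went from 6.18 ± 1.00 to 3.52 ± 1.11 TPM and Pvalb from 15.1 ± 2.70 to 9.48 ± 2.13. The calls of Actn3, Pvalb and Casq1 ended in 4, 6 and 8 of the 9 fits that left out 1 library (limma adjusted p of up to 0.0636, 0.0888 and 0.113). The muscle list was called lower (camera adjusted p = 4.52e-05; adjusted p = 0.378 with an estimated correlation). Of 11 matrix protease and remodelling genes, 6 rose (7 adjusted over the list alone), among them the protease inhibitor Timp1 from 8.07 ± 3.52 to 34.4 ± 5.31, the gelatinase Mmp9 from 5.05 ± 1.34 to 9.74 ± 2.05 and the urokinase receptor Plaur from 5.17 ± 0.847 to 9.28 ± 0.893 TPM (camera adjusted p = 4.02e-05; adjusted p = 0.157 with an estimated correlation). Of 18 fibroblast and collagen genes, Eln fell (52.2 ± 7.47 to 38.9 ± 3.71 TPM; 0 genes adjusted over the list alone) and 17 were not called, including Col3a1 with 368 ± 65.4 and 443 ± 58.3 TPM. The call of Eln ended in 8 of the 9 fits that left out 1 library (limma adjusted p of up to 0.107), and the fibroblast list had a camera adjusted p of 0.368.

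Settings other than a left-out library also ended calls of genes named here. With a pseudocount of 0.01, Ccnb1, Cxcl3, Stfa2l1, Ly6c2, Sprr2a2, Sprr2a1, Ccl3, Gzma and Fpr2 were not called (limma adjusted p of up to 0.121). The log2 fold changes of Ccl3 and Cxcl3 were then 4.34 and 5.47. With a pseudocount of 0.1, Ccnb1, Ly6c2, Sprr2a2 and Sprr2a1 were not called (limma adjusted p of up to 0.0682). Without an expression filter, Stfa1, Prr9, Foxp3, Dsc1, Pvalb, Ccr6, Tnfrsf4, Ly6c2, Kif20a, Msx2, Lcn2, Sprr2a1, Sprr2a2, Birc5, Eln, Casq1, Cstdc5, Cdk1, Ccnb1, Sbsn and Krt2 were not called (limma adjusted p of up to 0.514). With array weights, Msx2, Kif20a, Lcn2, Casq1, Ly6c2, Ccnb1, Pvalb, Cstdc5, Birc5, Cdk1, Ccr6 and Eln were not called (limma adjusted p of up to 0.0860). With robust variances, Il1b, Stfa1, Sprr2a1, Sprr2a2, Ly6c2, Lcn2 and Cstdc5 were not called (limma adjusted p of up to 0.0843). Without a variance trend, Ccnb1, Casq1, Cdk1 and Eln were not called (limma adjusted p of up to 0.0521). With quantile normalization, Cdk1, Ccnb1 and Krt2 were not called (limma adjusted p of up to 0.1198). With median scaling, Dsc1, Cdk1 and Ccnb1 were not called (limma adjusted p of up to 0.0578). Without the 50 most abundant genes in the total, Ccnb1 was not called (limma adjusted p = 0.0538). With the GC and length correction, Ccnb1, Krt2 and Eln were not called (limma adjusted p of up to 0.0569). Among protein-coding genes alone, Krt2 was not called (limma adjusted p = 0.0609). Tnf and Krt6b passed with a TPM minimum of 5, with quantile normalization, with the GC and length correction and among protein-coding genes alone (limma adjusted p of down to 0.0261 and 0.0254), and S100a8 and Krt6a among protein-coding genes alone (limma adjusted p = 0.0446 and 0.0453).

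Over the 46 lists tested, camera called 23 higher and 11 lower with its preset correlation of 0.01. With an estimated correlation it called 0, and 10 lists had an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, called 16 lists higher and 4 lower at a Benjamini-Hochberg adjusted p under 0.05. With the preset correlation, the GC and length correction gave 19 lists higher and 8 lower, and a TPM minimum of 5 gave 20 and 8. Camera no longer called the basal keratinocyte list at a TPM minimum of 5, without a variance trend or with the GC and length correction (adjusted p = 0.0655, 0.0532 and 0.147). With the muscle covariate, the interleukin-17-responsive, interferon-gamma response and muscle lists were not called (adjusted p = 0.210, 0.207 and 0.663), and the fibroblast list was called higher (adjusted p = 0.0172). With the hair follicle covariate, the basal keratinocyte and hair follicle lists were not called (adjusted p = 0.266 and 0.857), and the dendritic and Langerhans cell list was called higher (adjusted p = 0.0158). Each covariate is the mean of its own list, so the lost calls of the muscle and hair follicle lists follow from the fit and are not results. The 16 single genes fixed in advance were also compared by the exact two-sided permutation test, whose smallest possible p is 0.00794. On log2(TPM + 1), 8 of these had a p under 0.05, and the lowest adjusted p over the 16 was 0.0635, so none passed the correction by this test. Without replicate 5 of the bacterium alone, 10 had a p under 0.05 and all 10 passed (adjusted p = 0.0457). All 10 tied at the smallest p that this smaller set of libraries can give, 0.0286, so passing rested on the number of ties. Replicate 5 also held the highest Ifng and Il17f values of its group. With any other library left out none passed, and without anti-CTLA-4 replicate 2 or 3 only 5 had a p under 0.05. On mean TPM with all 9 libraries, 9 of the 16 had an exact permutation p under 0.05. That p was 0.00794 for Ctla4, Cd8a, S100a8, Lcn2 and Krt6a. The p-values on mean TPM were not adjusted over the panel, so the absence of passing genes holds for log2(TPM + 1) only.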

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

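Single libraries stood apart from their group in 19 of 422 groups of values looked at (4.5%), where chance gives about 1 in 20, so the number is no larger than chance gives. Each had a gap to its nearest neighbour that was large for the range of its group by Dixon's test.

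Among the libraries of the bacterium alone, replicate 5 had 2.48 TPM of Cxcl3 where the other 4 lay between 0 and 0.341. It also had 2.04 TPM of Ifng (others 0.12 to 0.28) and 3.35 TPM of Aim2 (others 2.36 to 2.58). Replicate 1 had 61.7 TPM of Mcpt4 (others 82.2 to 91.7), 37.5 of Aloxe3 (others 29.0 to 30.9) and 39.5 of Abca12 (others 28.6 to 30.4). Its mean log2(TPM + 1) was 9.26 for the cornified envelope list (others 8.75 to 8.87) and 5.56 for the ceramide list (others 5.34 to 5.38). Replicate 4 had 12.4 TPM of Kif20a (others 15.7 to 16.9) and 14.6 of Col11a2 (others 8.31 to 9.58). Replicate 3 had a mean of 5.49 for the nuclear-encoded respiratory chain list (others 5.37 to 5.40).

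Among the anti-CTLA-4 libraries, replicate 4 had 40.1 TPM of Sprr2a3 where the other 3 lay between 16.7 and 19.0. Its mean log2(TPM + 1) was 6.11 for the fibroblast list (others 6.23 to 6.25) and 3.41 for the cartilage list (others 2.99 to 3.05). Replicate 1 had 19.8 TPM of Casq1 (others 12.7 to 13.4), 9.14 of Tnfrsf4 (others 11.8 to 12.3) and 91.5 of Orm1 (others 115 to 117). Replicate 2 had 16.6 TPM of Pdgfra (others 21.9 to 23.1), and replicate 3 had 24.0 of Grhl3 (others 21.0 to 21.4).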

How the results depend on the processing

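The fits on protein-coding genes and with the GC and length correction were chosen after the data were seen. None of the 1828 changed genes reversed in any fit that tested it. Skeletal muscle as a covariate gave 9 genes higher and 3 lower, 5 and 1 of them by at least 2-fold, and 7 lists lower. It also turned 2 values around, Cxcl1 to -0.44 and the median of the muscle list to 0.085. The second follows from the covariate being that list's own mean, and for Cxcl1, which was not called either way, the cause was not tested. Hair follicle as a covariate gave 1 gene higher and 1 lower, 1 and 1 by at least 2-fold, and 7 lists lower. Both covariates go with the group, which widens the SE. Lower genes numbered 1429 with quantile normalization, 1313 with median scaling, 1301 without the 50 most abundant genes, 1468 with the GC and length correction and 1260 at a threshold of 0.1. Genes lower by at least 2-fold numbered 13 without a filter, 11 among protein-coding genes and 13 with the GC and length correction. The fits on protein-coding genes, with and without the correction, leave out small RNA genes, which lowers this count, and for the fit without a filter the cause was not tested. Lists called were 0 higher and 0 lower with an estimated correlation, and fry called 4 lower. The GC and length correction gave 19 lists higher and 8 lower, and a TPM minimum of 5 gave 20 and 8. Of the 1828 calls, 1769 held with a pseudocount of 0.1, 1755 with 0.01, 1408 without a filter and 1634 with array weights.

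Leaving out 1 library gave 706 to 1094 genes higher, 337 to 703 lower, 137 to 243 higher and 14 to 21 lower by at least 2-fold, 20 to 24 lists higher, 8 to 12 lists lower, and 5 to 10 of the panel genes with an exact permutation p under 0.05 (8 with all libraries). Fewer samples lower the power of these fits. Some named genes near the filter (Ccr8, Cd6, Cd79b, Chil3, Fasl, Gzma, Stat4 and Stfa2l1) were not tested when any anti-CTLA-4 library was left out, nor was the list of B and plasma cells. Depth is unknown for TPM, which limits what can be said of genes near 1 TPM.

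The expression values gave no sign that the replicate numbers pair the libraries. The deviations of same-numbered libraries from their group means correlated across genes at -0.0086, 0.018, -0.091 and -0.0933. No anti-CTLA-4 library correlated best with the bacterium-alone library of its own number. All pairs across the groups lay between -0.0933 and 0.0985, so a weak or partial pairing could go unseen. With the replicate block limma called 593 genes higher and 88 lower, 11 of the latter by at least 2-fold, and 638 of the 1828 calls held. The block uses up degrees of freedom, and replicate 5, which has no partner, then adds nothing to the comparison.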

Other observations

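Tests of the microRNA, keratinocyte dilution, ribosomal RNA, muscle, T cell and interferon patterns were chosen after the results were seen, and the rules for reading the dilution, muscle, T cell and interferon tests were revised after their values were known, which moved the interferon comparison from excluded, and those of Ctla4 and of Cd8a with Cd4 from favoured, to undecided. The rules for reading the regroupings of the libraries and the GC and length correction were written before the results of those tests. The correction itself was added after the data were seen.

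Some mast cell and complement genes rose in the anti-CTLA-4 group. Of 11 mast cell genes, 4 rose (4 higher and 1 lower adjusted over the list alone). The histamine-forming enzyme Hdc rose from 5.20 ± 1.10 to 10.8 ± 1.39 TPM (SD, n = 5 and n = 4), and the mast cell proteases Cma1, Cpa3 and Mcpt4 from 43.6 ± 7.90 to 64.9 ± 6.89, from 11.4 ± 2.11 to 15.9 ± 0.955 and from 82.0 ± 12.1 to 115 ± 14.9. The last 3 lost their call in 4, 7 and 6 of the 9 fits that left out 1 library (limma adjusted p of up to 0.0677, 0.0954 and 0.102). The list was called higher (camera adjusted p = 0.0150; adjusted p = 0.378 with an estimated correlation). Of 12 complement and acute phase genes, 6 rose and 1 fell (7 higher and 1 lower adjusted over the list alone), with Saa3, C1s1 and C1ra among those rising and Orm1, named after its values were seen, going from 138 ± 6.32 to 110 ± 12.3 TPM (camera adjusted p = 0.000223; adjusted p = 0.208 with an estimated correlation). The call of Orm1 ended in 4 of the 9 fits that left out 1 library (limma adjusted p of up to 0.0698). Of 14 type 2 immunity genes, the chitinase-like Chil3 rose from 0.350 ± 0.266 to 1.72 ± 0.405 TPM (4 genes adjusted over the list alone), and the list was called higher (camera adjusted p = 0.0261; adjusted p = 0.247 with an estimated correlation). That call of the list ended in 4 of the 9 fits without 1 library (adjusted p of up to 0.0989), at a TPM minimum of 5 (0.111), with the muscle covariate (0.0879) and with the GC and length correction (0.0599). The mast cell call ended with the hair follicle covariate (adjusted p = 0.0927) and with the GC and length correction (0.0599).

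All 13 circadian clock genes had a negative log2 fold change, with a median of -0.30, and Per3 fell from 21.0 ± 3.92 to 14.4 ± 2.12 TPM (2 genes adjusted over the list alone; camera adjusted p = 0.000202 for the list; adjusted p = 0.376 with an estimated correlation). The call of Per3 ended in 7 of the 9 fits without 1 library (limma adjusted p of up to 0.110), and the time of day of collection is not given in the sources used here. Of 14 immediate early and heat shock genes, Atf3 rose from 3.46 ± 0.576 to 6.07 ± 0.523 TPM and Jun fell from 162 ± 15.1 to 131 ± 9.37 (1 higher and 1 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.604). The call of Jun ended in 6 of the 9 fits without 1 library (limma adjusted p of up to 0.113).

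In the remaining lists few genes were called, and those named here were chosen after their values were seen. Camera called 3 of these lists higher. Endothelial activation had 1 of 6 genes rise, Vcam1 (2 adjusted over the list alone; adjusted p = 0.0426; adjusted p = 0.378 with an estimated correlation). Glycolysis and hypoxia had 1 of 16, Pkm (1 adjusted over the list alone; adjusted p = 0.0101; adjusted p = 0.443 with an estimated correlation). The nuclear-encoded respiratory chain had 0 of 18 called (0 adjusted over the list alone; adjusted p = 0.00449; adjusted p = 0.434 with an estimated correlation). Camera called 4 lists lower. Adipocytes had 1 of 13 genes fall, Pparg (1 adjusted over the list alone; adjusted p = 0.0150; adjusted p = 0.443 with an estimated correlation). Cartilage had 1 of 13, Col11a2 (0 adjusted over the list alone; adjusted p = 0.0309; adjusted p = 0.539 with an estimated correlation). Nerve and Schwann cells had 0 of 9 called (0 adjusted over the list alone; adjusted p = 0.0319; adjusted p = 0.443 with an estimated correlation), and melanocytes 0 of 5 (0 adjusted over the list alone; adjusted p = 0.0393; adjusted p = 0.418 with an estimated correlation). Leaving out 1 library ended these calls in 3 fits for endothelial activation, 3 for cartilage, 3 for nerve and 6 for melanocytes, without replicate 2 of the bacterium alone or anti-CTLA-4 replicate 3 for adipocytes, and without replicate 4 of the bacterium alone for glycolysis, with adjusted p-values of up to 0.0922, 0.199, 0.106, 0.1203, 0.150 and 0.0605. The lists of B and plasma cells (Cd79b higher, 1 of 3 genes), red cells and platelets (Pf4 higher, 1 of 5), sebaceous gland (Scd1 lower, 1 of 11), lymphatic endothelium (Lyve1 and Pdpn higher, 2 of 7), smooth muscle and pericytes (Notch3 lower, 1 of 7), blood vessel endothelium (0 of 11) and ribosomal proteins (0 of 20) were not called, with camera adjusted p-values of 0.0605, 0.103, 0.0615, 0.528, 0.553, 0.717 and 0.627. Adjusted over each list alone, the counts were 1, 1, 0, 2, 1 higher and 1 lower, 0 and 0. The called B and plasma cell gene averaged under 1 TPM with the bacterium alone and at least 1 TPM with the antibody. The calls of Vcam1, Pkm, Pparg, Col11a2, Scd1, Lyve1, Pdpn and Notch3 ended in 6, 6, 6, 7, 7, 7, 7 and 5 of the 9 fits without 1 library, with limma adjusted p-values of up to 0.0973, 0.0853, 0.0888, 0.121, 0.106, 0.0852, 0.0917 and 0.0711. The sebaceous gland list was called lower without replicate 1 or 3 of the bacterium alone or at a TPM minimum of 5 (camera adjusted p of down to 0.0161), and that of B and plasma cells higher without an expression filter (camera adjusted p = 0.0153). For blood vessel endothelium the median (-0.019) and the mean (0.011) of the log2 fold changes differ in sign.

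Other settings ended further calls of the lists and genes above that the main comparison does not name. The GC and length correction ended those of endothelial activation, cartilage, nerve and the respiratory chain (camera adjusted p = 0.102, 0.112, 0.0503 and 0.128). A TPM minimum of 5 ended cartilage and nerve (0.0949 and 0.09002), and array weights endothelial activation and cartilage (0.0508 and 0.0687). Endothelial activation was also not called with quantile normalization, median scaling or no expression filter (camera adjusted p of up to 0.0615). The muscle covariate ended endothelial activation, cartilage, nerve, the respiratory chain, adipocytes and glycolysis (camera adjusted p = 0.262, 0.239, 0.1803, 0.0639, 0.747 and 0.436), and the hair follicle covariate endothelial activation, nerve, the respiratory chain and melanocytes (0.343, 0.0801, 0.283 and 0.309). With a pseudocount of 0.01, Chil3 was not called (limma adjusted p = 0.0581). Without an expression filter, Lyve1, Pparg, Jun, Vcam1, Pdpn, Cpa3, Mcpt4, Per3, Col11a2 and Scd1 were not called (limma adjusted p of up to 0.0909). With array weights, Col11a2, Jun, Pkm, Pdpn and Lyve1 were not called (limma adjusted p of up to 0.0777). With robust variances, Jun was not called (limma adjusted p = 0.0521). Without a variance trend, Col11a2 was not called (limma adjusted p = 0.0524). With quantile normalization, Vcam1 was not called (limma adjusted p = 0.0534). With the GC and length correction, Mcpt4, Col11a2 and Cpa3 were not called (limma adjusted p of up to 0.0591).

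Regrouping the 9 libraries into 5 and 4 in other ways gives a measure of chance. Of 100 splits drawn, the real one included, 1 gave as many changed genes as the real split, which was the real split itself. It called 1828 genes where the highest other split called 7. The same held for genes higher (1124 against 3), lower (704 against 4), higher by at least 2-fold (197 against 3) and lower by at least 2-fold (21 against 4), each with 1 split of the 100. A chance split of these libraries is therefore unlikely to give such counts. The splits cannot tell the antibody apart from any other difference shared by the libraries of a group. For the counts of lists, chance remains possible. The 23 lists called higher were matched or exceeded in 9 of the 100 splits, with 25 in the highest other, and the 11 called lower in 29 of the 100, with 25 in the highest other.

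The smallest p in the table belongs to Mir3112, whose value fell from 8.02 ± 0.592 to 0 TPM. The values correspond to at most 1 inferred read in any library, present in all 5 libraries of the bacterium alone and in none of the others. A candidate explanation is single reads on a very short feature, for which the fitted error is too small. A biological fall was not tested separately, and 20 of 457 microRNA genes tested were called.

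The lower level of cholesterol synthesis and cornified envelope genes could come from dilution of keratinocyte RNA by infiltrating immune cells. Which cells express the cholesterol genes was not tested. The mean of the cholesterol list fell by more than that of the basal keratinocyte list, by -0.22 on the log2 scale (exact permutation p = 0.00794, the smallest it can give; adjusted p = 0.0317 over 6 such tests). This argues only against a dilution that lowers the cholesterol and basal keratinocyte lists alike. The cornified envelope list mean fell by -0.40 (exact permutation p = 0.0159) and the cholesterol list mean by -0.36, so a smaller share of differentiated keratinocytes stays open. For the cornified envelope list the difference from the basal list was -0.26 (exact permutation p = 0.119; adjusted p = 0.143), the basal list itself did not pass (-0.14; exact permutation p = 0.0556), and dilution cannot be told apart from a change in those genes with 9 libraries. Bias from GC content or length and the ribosomal RNA share are argued against as the whole cause. The cholesterol list's median log2 fold change was -0.386 with the correction and -0.407 without the 50 most abundant genes, against -0.386 as reported. The medians of all tested genes were -0.034, -0.032 and -0.014. After the correction 16 cholesterol genes were called lower, against 13 among the same 13904 genes without it, and 17 without the 50 most abundant genes against 13 as reported. These counts are weaker evidence, since both settings called more genes lower in all (1468 and 1301, against 704 in the main fit). No biological explanation was tested.

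The lower skeletal muscle genes could reflect a smaller share of muscle in the dissected piece, although the fall of the list mean itself, -0.35 on the log2 scale, did not pass (exact permutation p = 0.0556). If all muscle transcripts were lost alike, their log2 fold changes would scatter no more than in other splits. Their SD was 0.193 and their variance was larger than in most splits (exact permutation p = 0.0317; adjusted p = 0.0476 over the 6 tests), from -0.69 for Actn3 to -0.069 for Tpm2. This argues against an equal loss of all muscle transcripts as the whole cause. A loss that differs between fibre types, or that other cells expressing some of these genes mask, stays open.

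Within T cell genes, Cd8a rose by more than Cd4, by 1.77 on the log2 scale (exact permutation p = 0.0159; adjusted p = 0.0317 over the 6 tests). The pair was chosen after both values were seen and Cd8a is the largest rise in the T cell list, so this does not test whether CD8 T cells take a larger part of the rise, which stays open. Cd8b1, chosen after its values were seen, rose from 0.541 ± 0.366 to 4.38 ± 1.14 TPM (SD, n = 5 and n = 4; limma adjusted p = 0.00220), while the dendritic cell markers Itgax, Clec9a and Xcr1 had log2 fold changes of 0.35, 0.25 and 0.17 and were not called (limma adjusted p = 0.107, 0.206 and 0.433). Ctla4 rose by 0.76 more than the mean of the T cell list (exact permutation p = 0.0159; adjusted p = 0.0317), but 2 members of that list rose by more than Ctla4, so this says nothing of Ctla4 per cell. The type I interferon list rose by 0.30 more than the interferon-gamma list on average (exact permutation p = 0.262; adjusted p = 0.262), a difference within the spread between libraries, so these data do not show which response is stronger.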
